A study of Mus musculus with 9 samples.

How the data were processed

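Total RNA from 9 samples of NIH-3T3 mouse fibroblasts was measured, 1 Affymetrix mouse genome array per sample. All samples had received H-RasV12 by retrovirus, 3 of them no further construct, 3 of them C/EBPβ and 3 of them C/EBPβ-UTR. After drug selection the cells were plated at equal density and harvested 48 to 72 h later, and biotin-labelled cRNA was made by priming from the poly(A) tail. The deposited values are log2 signals that the authors computed from the scans by robust multi-array average (RMA), with no software version given. RMA includes background correction, quantile normalization and a summary per probe set. The 9 columns ranged from 1.88 to 14.3 and had medians of 5.22 to 5.28 over 45101 probe sets, which fits log2 values that had been brought to 1 distribution, and they were used as deposited. The scans, detection calls and scan dates were not used, so that no batch could be looked for beyond the replicate number.

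Groups were taken from the sample titles. The genotype fields of RasV12 replicates 2 and 3 read H-RasV13 and H-RasV14 where the titles read RasV12, and the titles were followed. The labels do not say whether the replicates were separate infections or cultures, so each p-value measures the spread between these samples only. No construct sequence is given, and C/EBPβ-UTR is the label's own name. No pair of arrays was a duplicate of another. After subtraction of the group means, arrays with the same replicate number in different groups correlated by -0.235 to 0.0452 across genes, so that the number was not taken to mark pairs.

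Of the 45101 probe sets, 64 controls, 932 with several gene symbols and 9160 with none were left out. The remaining 34945 represented 18193 genes, each by the probe set with the highest mean over the 9 arrays. No filter on dim genes was applied. Without detection calls a signal is not shown to be above background, so no fold change is given for a gene whose lower group lies below the median of 6.32, only the difference of its log2 signals, and counts at a fold threshold are counts of such differences. The model was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided tests) to all 9 arrays, with a mean for each group and 11.3 degrees of freedom in all, residual and prior. The comparisons were CEBPB minus RasV12, CEBPB-UTR minus RasV12, and CEBPB minus CEBPB-UTR, which is also the test of whether the first 2 differ. P-values were adjusted by Benjamini-Hochberg over all genes of a comparison, and a gene was called at an adjusted p under 0.05. With 3 arrays against 3 a two-sided permutation test of a single gene cannot give less than 0.1, so the calls rest on the spread that limma shares across genes. At an unadjusted p under 0.05 the 3 comparisons held 5214, 5858 and 6613 genes. Each Cebpb probe set was tested in a fit to all probe sets. Figures were drawn with matplotlib 3.10.9.

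The 21 program lists and 5 marker lists, with 535 genes of which 493 were measured, were written from general knowledge before the data were examined, as were the comparisons, tests, alternatives and the rule for naming genes. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 63 program tests together and the 15 marker tests apart. With a correlation estimated for each list, 0 of the 34 program calls held, the lowest adjusted p of a program list being 0.16. Directional fry, which tests whether a list's genes move on balance one way and makes no comparison with other genes, called 33 of the 34 and another 14 that camera did not, 3 of them tests of marker lists. A list is called in the text where camera with its preset correlation passes, unless fry is named. The median, the mean and the test differed in sign in 12 of the 78 list tests, and 0 of those 12 were called. Besides each adjusted count, members were counted again adjusted over the list alone.

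Genes were named by rule. Per comparison these were the 8 largest rises and the 8 largest falls among genes with an adjusted p under 0.05, arrays that did not overlap between the groups (chance gives 10% of genes such a separation at 3 against 3), a mean in the brighter group above the median of 6.32 and no clone-type symbol. Cebpb and up to 4 members with the smallest adjusted p of each described list were added. List members named beside counts of 5 or fewer, where they fall outside this rule, were chosen after their values were seen. So were the growth factor genes described in the closing section, the members given as the largest rises of the uncalled growth factor list, and the genes named in the closing section for the opposite calls, the Sprr family and the implied shares.

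The alternatives tried were leaving out the genes below the median signal, a further quantile normalization, centring each array on its median, an offset of 32 before the logarithm, the mean of a gene's probe sets, all probe sets, eBayes with trend and robust options, array weights, a fit to only the 6 arrays compared, the replicate number as a block, each array left out in turn, and for lists the estimated correlation and fry. The pipeline was tested on simulated data in which 50 genes per fold change were altered among 18193. It recovered 44%, 40% and 18% of the 1.25-fold changes, in the order of the comparisons above, at least 92% of the 1.5-fold changes and 100% of the 2-fold changes, and it called 7, 8 and 17 unchanged genes. A list shifted by 0.3 was called in each of the 3 comparisons, with 0 other lists. The simulated genes were independent, whereas the shifted list, mitosis, had an estimated correlation of 0.43 in the data. The simulation therefore cannot show list calls that arise from correlated members.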

Results

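Gene expression was measured in NIH-3T3 cells, an established mouse fibroblast line, that carried H-RasV12, a constitutively active form of the small GTPase H-Ras introduced with a retrovirus. The 9 samples formed 3 groups of 3 arrays: RasV12 alone, RasV12 with a retrovirus for C/EBPβ (CEBPB below), and RasV12 with a retrovirus for the construct called C/EBPβ-UTR (CEBPB-UTR below). C/EBPβ is a basic leucine zipper transcription factor, encoded by Cebpb. The series asks how the 3' untranslated region (UTR) of its mRNA alters the expression program of Ras-transformed cells. As background from knowledge of the study, the UTR construct is the one that carries this region, which the labels do not spell out. Values were log2 signals for 18193 genes, and each group mean rests on only 3 arrays. Across genes, which are not independent replicates, Pearson r was 0.996 to 0.999 between arrays of a group and 0.981 to 0.994 between arrays of different groups. On the first principal component, with 58.0% of the variance, CEBPB replicates 1 and 2 lay at 36.8 and 39.0 and CEBPB replicate 3 at 19.6, between them and the other 6 arrays, which all had negative values.

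Cebpb itself was read by 2 probe sets, both of them higher with CEBPB-UTR and 1 of them with CEBPB. Probe set 1427844_a_at had a mean log2 signal of 8.92 ± 0.15 in RasV12, 10.12 ± 0.08 in CEBPB and 10.66 ± 0.15 in CEBPB-UTR (SD, n = 3 each). Its rise over RasV12 was 2.29-fold with CEBPB (adjusted p = 1.0e-05) and 3.34-fold with CEBPB-UTR (adjusted p = 3.0e-06), and it was lower in CEBPB than in CEBPB-UTR, with a log2 difference of -0.54 (95% interval -0.76 to -0.33, adjusted p = 0.0023). Probe set 1418901_at read 10.44 ± 0.12, 10.60 ± 0.03 and 11.80 ± 0.09 in the same order. It was 2.56-fold higher with CEBPB-UTR (adjusted p = 4.2e-06), whereas with CEBPB its log2 change was 0.16 (95% interval -0.02 to 0.33, adjusted p = 0.28). The probe set with the higher mean signal, 1418901_at, stands for Cebpb in the counts and lists that follow.

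**Figure D1:**
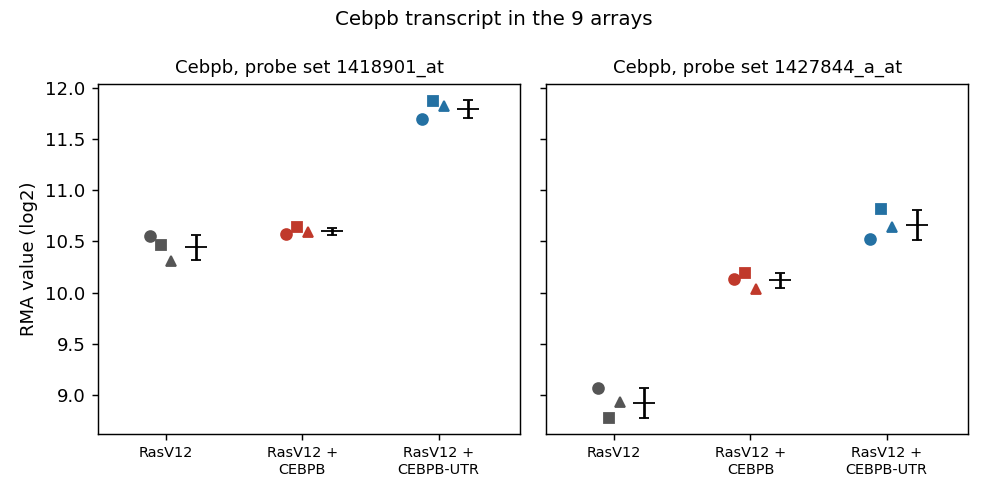
Log2 signal of the 2 Cebpb probe sets on each of the 9 arrays, by group, with the mean and SD (n = 3) of each group. With CEBPB, 1427844_a_at lay at 10.12 against 8.92 in RasV12, while 1418901_at lay at 10.60 against 10.44.

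CEBPB was first compared with RasV12 alone, which asks what this construct, together with its retrovirus, adds to the program of Ras-transformed fibroblasts. The largest rises were those of Lcn2, Stfa3 and S100a8. Lcn2, the siderophore-binding lipocalin of the acute phase (probe set 1427747_a_at), rose from 3.77 ± 0.28 to 12.27 ± 1.12 (mean log2 signal, SD, n = 3; adjusted p = 1.0e-07), with 10.98 on CEBPB replicate 3 against 12.85 and 12.98 on the other CEBPB arrays. Stfa3, a cysteine protease inhibitor of the stefin family (1419709_at), had a log2 change of 8.40 ± 0.17 (SE, adjusted p = 9.3e-11), and S100a8, a subunit of calprotectin (1419394_s_at), had one of 8.05 ± 0.14 (SE, adjusted p = 4.7e-11). The RasV12 signals of these genes lay below the median of 6.32 and are not shown to be above background. Of 25 mitosis genes 19 fell, by smaller amounts.

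Other large rises, as log2 change ± SE with n = 3 per group, were those of Sprr1b (7.65 ± 0.48) and Sprr2h (6.03 ± 0.68), precursors of the cornified envelope, Retnla (7.25 ± 0.18), a secreted resistin-like protein, Serpinb2 (6.52 ± 0.24), the plasminogen activator inhibitor of type 2, and Clec4e (6.21 ± 0.16), a C-type lectin receptor. The largest falls were those of Myh1 (-3.89 ± 0.32), a myosin heavy chain, Scg2 (-3.08 ± 0.24), a secretogranin, Itgbl1 (-2.60 ± 0.24), an integrin beta-like protein, Dkk2 (-2.58 ± 0.19), a Wnt antagonist, Edil3 (-2.23 ± 0.19), an integrin-binding matrix protein, Tafa1 (-2.16 ± 0.27), a small secreted protein, Fgd4 (-2.13 ± 0.34), an exchange factor for Cdc42, and Endod1 (-2.12 ± 0.19). Adjusted p for these genes ran from 4.2e-10 for Retnla to 0.0011 for Fgd4. Of the falls, 2 of 3 probe sets were called lower for Myh1, 2 of 6 for Edil3 and 3 of 5 for Fgd4. Of the rises, Clec4e had 2 probe sets, both called higher, with log2 changes of 2.43 and 6.21. Without CEBPB replicate 3 the log2 changes were 9.14 for Lcn2, 8.44 for Sprr1b and 7.16 for Sprr2h. At an adjusted p under 0.05, 1457 genes were higher and 1890 lower with CEBPB, 3347 of 18193. Of these, 319 rose and 140 fell at least 2-fold, and 98 rose at least 4-fold. The 140 became 79 with an offset of 32 before the logarithm and 93 with probe sets averaged, and the 98 became 59 with the offset and 61 without the genes of below-median signal.

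Inflammatory cytokines and chemokines rose with CEBPB, 16 of 23 measured members against 1 that fell, Ccl8 (-0.26 ± 0.07). The members with the smallest adjusted p were Lif (3.42 ± 0.10), Cxcl5 (5.24 ± 0.29), Ptgs2 (2.25 ± 0.13), the inducible cyclooxygenase, and Cxcl1 (4.98 ± 0.33). 16 rose and 1 fell adjusted over the list alone (camera adjusted p = 7.2e-11, and adjusted p = 0.16 with an estimated correlation). Among acute phase and innate defence genes 11 of 21 rose and 0 fell, with Ptx3 (4.76 ± 0.22), a pentraxin, and Cd14 (1.87 ± 0.13), the lipopolysaccharide co-receptor, beside S100a8 and Lcn2. 11 rose and 0 fell adjusted over the list alone (camera adjusted p = 7.2e-11, and adjusted p = 0.16 with an estimated correlation). Extracellular matrix genes rose in 15 of 27 cases, led by Thbs1 (4.13 ± 0.09), which encodes thrombospondin, Fn1 (1.49 ± 0.08), fibronectin, Col5a2 (1.94 ± 0.12) and Lox (2.83-fold), while Fbln2, Col6a1, Col6a2 and Col6a3 fell. 16 rose and 4 fell adjusted over the list alone (camera adjusted p = 2.0e-06, and adjusted p = 0.16 with an estimated correlation). Of 18 matrix proteases and their inhibitors 8 rose, among them Serpinb2, Mmp3 (2.97 ± 0.23), Timp1 (0.87 ± 0.08) and Mmp2 (0.64 ± 0.07), and Plat, Timp3 and Mmp14 fell. 9 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.00053, and adjusted p = 0.16 with an estimated correlation). Growth factors of the EGF, FGF and related families also rose, 7 of 17, with Hgf (2.30 ± 0.13), Fgf7 (1.91 ± 0.08), Ereg (1.34 ± 0.08) and Nrg1 (1.04 ± 0.10), and Tgfb3 and Pdgfa fell. 8 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.017, and adjusted p = 0.16 with an estimated correlation). Without the genes of below-median signal this list was not called (adjusted p = 0.085).

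Cell cycle transcripts fell with CEBPB. Of 25 measured mitosis genes 19 fell and 0 rose, with Plk1 (-0.57 ± 0.07), the mitotic Polo-like kinase, Cenpa (-0.58 ± 0.07), the centromeric histone, Ccnb2 (-0.68 ± 0.09) and Mki67 (-0.44 ± 0.07). 0 rose and 24 fell adjusted over the list alone (camera adjusted p = 2.4e-11, and adjusted p = 0.16 with an estimated correlation). Of 29 genes of DNA replication and S phase 16 fell and 0 rose, with Lig1 (-0.73 ± 0.08), a DNA ligase, Pola1 (-0.61 ± 0.08), a subunit of DNA polymerase alpha, and the helicase subunits Mcm6 (-0.56 ± 0.07) and Mcm3 (-0.56 ± 0.08). 1 rose and 21 fell adjusted over the list alone (camera adjusted p = 5.0e-08, and adjusted p = 0.16 with an estimated correlation). Among p53 targets and CDK inhibitors 10 of 23 rose, with Btg2 (1.51 ± 0.12), Mdm2 (0.60 ± 0.06), Cdkn2c (1.01 ± 0.11) and Plk2 (1.51 ± 0.17), and 2 fell, Cdkn1b (-0.57 ± 0.15) and Zmat3 (-0.27 ± 0.08). 11 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.00026, and adjusted p = 0.16 with an estimated correlation). Cholesterol synthesis enzymes fell in 11 of 16 cases, with Fdft1 (-0.45 ± 0.06), squalene synthase, Msmo1 (-0.68 ± 0.11), Mvd (-0.45 ± 0.09) and Lss (-0.38 ± 0.08), and Hsd17b7 (0.34 ± 0.09) rose. 1 rose and 12 fell adjusted over the list alone (camera adjusted p = 6.3e-05, and adjusted p = 0.16 with an estimated correlation).

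The remaining 5 called lists were these. Of 24 genes of the ATF4 pathway and unfolded protein response 12 rose, with Ddit3 (1.34 ± 0.12), the transcription factor CHOP, Dnajb9 (0.86 ± 0.09), Ddit4 (0.75 ± 0.08) and Slc7a11 (3.14 ± 0.49), a cystine transporter that the list of NRF2 targets also holds, with 3.92 when CEBPB replicate 3 was left out, and Phgdh fell. 12 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00030, and adjusted p = 0.29 with an estimated correlation). Of 17 NRF2 targets and oxidative stress genes 7 rose, with Hmox1 (1.29 ± 0.11), heme oxygenase, Sod2 (1.51 ± 0.18) and Abcc1 (0.67 ± 0.09), and 2 fell, Gstm1 (-0.89 ± 0.13) and Gsta4. 8 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.010, and adjusted p = 0.21 with an estimated correlation). Adipocyte genes rose in 8 of 19 cases, with Lpl (4.88 ± 0.30), lipoprotein lipase, Cd36 (5.23 ± 0.44), a fatty acid and scavenger receptor with 5.95 when CEBPB replicate 3 was left out, Retn (0.82 ± 0.11) and Plin2 (0.61 ± 0.09), and Fasn (-0.26 ± 0.08) fell. 8 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.0025, and adjusted p = 0.16 with an estimated correlation). Lysosomal genes rose in 8 of 19 cases and 0 fell, with Ctsk (0.85 ± 0.09), Gla (0.63 ± 0.12), Ctsd (0.34 ± 0.07) and Npc2 (0.42 ± 0.09). 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.012, and adjusted p = 0.16 with an estimated correlation). Immediate early and MAPK feedback genes went both ways. In that list 11 of 24 rose, with Ier3 (1.49 ± 0.09), Junb (0.84 ± 0.09), Egr1 (1.20 ± 0.15) and Fos (0.88 ± 0.12), and 5 fell, Etv5, Spred1, Egr3, Spred2 and Fosb. 13 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.0069, and adjusted p = 0.16 with an estimated correlation). With all probe sets tested the MAPK list was not called (adjusted p = 0.51).

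The other 7 program lists were not called by camera in this comparison. Of these, 2 were called by fry, the cytosolic ribosomal proteins downward (fry adjusted p = 0.0010) and the C/EBP family upward (fry adjusted p = 0.012). Of 20 contractile and SRF target genes, 4 rose (Ccn1, Ankrd1, Tagln and Ccn2) and 6 fell, 4 and 6 adjusted over the list alone, with adjusted p = 0.40. The median log2 change of that list was -0.11 and its mean 0.08, and the test ran in the downward direction. Of 20 glycolysis and hypoxia genes, 4 rose (Adm, Slc2a1, Pfkp and Hk2) and 2 fell (Egln3 and Pdk1), 4 and 3 adjusted over the list alone, with adjusted p = 0.43. Of 21 interferon-stimulated genes, 1 rose (Cxcl10) and 3 fell (Ifit2, Ifit1 and Ifit3), 1 and 3 adjusted over the list alone, with adjusted p = 0.85. Of 19 Notch, Wnt and Hedgehog targets, 1 rose (Lef1) and 1 fell (Ccn4), 1 and 1 adjusted over the list alone, with adjusted p = 0.67. Of 17 cytosolic ribosomal proteins, 0 rose and 2 fell (Rpl14 and Rps16), 0 and 2 adjusted over the list alone, with adjusted p = 0.18. Of 22 ribosome biogenesis genes, 2 rose (Utp4 and Tsr1) and 1 fell (Dkc1), 2 and 1 adjusted over the list alone, with adjusted p = 0.85. Of 5 C/EBP family genes, 1 rose (Ddit3) and 0 fell, 1 and 2 adjusted over the list alone, with adjusted p = 0.68.

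None of the 5 lists of cell type markers was called by camera in any of the 3 comparisons, the lowest adjusted p being 0.38. Fry called the macrophage markers upward with CEBPB against RasV12, and the skeletal muscle markers downward with CEBPB and with CEBPB-UTR against RasV12 (fry adjusted p = 0.037 each). Of 14 macrophage markers, 2 rose (Cd53 and Lyz2) and 0 fell, 2 and 0 adjusted over the list alone, with adjusted p = 0.38. Of 14 epithelial markers, 0 rose and 0 fell, 0 and 0 adjusted over the list alone, with adjusted p = 0.95. Of 12 endothelial markers, 0 rose and 1 fell (Tie1), 0 and 1 adjusted over the list alone, with adjusted p = 0.80. Of 13 skeletal muscle markers, 0 rose and 3 fell (Chrna1, Tnni1 and Acta1), 0 and 3 adjusted over the list alone, with adjusted p = 0.46. Of 14 fibroblast markers, 1 rose (Pdpn) and 3 fell (Pdgfra, S100a4 and Vim), 3 and 3 adjusted over the list alone, with adjusted p = 0.74. Without CEBPB replicate 3 the count of changed genes was 3592.

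**Figure D2:**
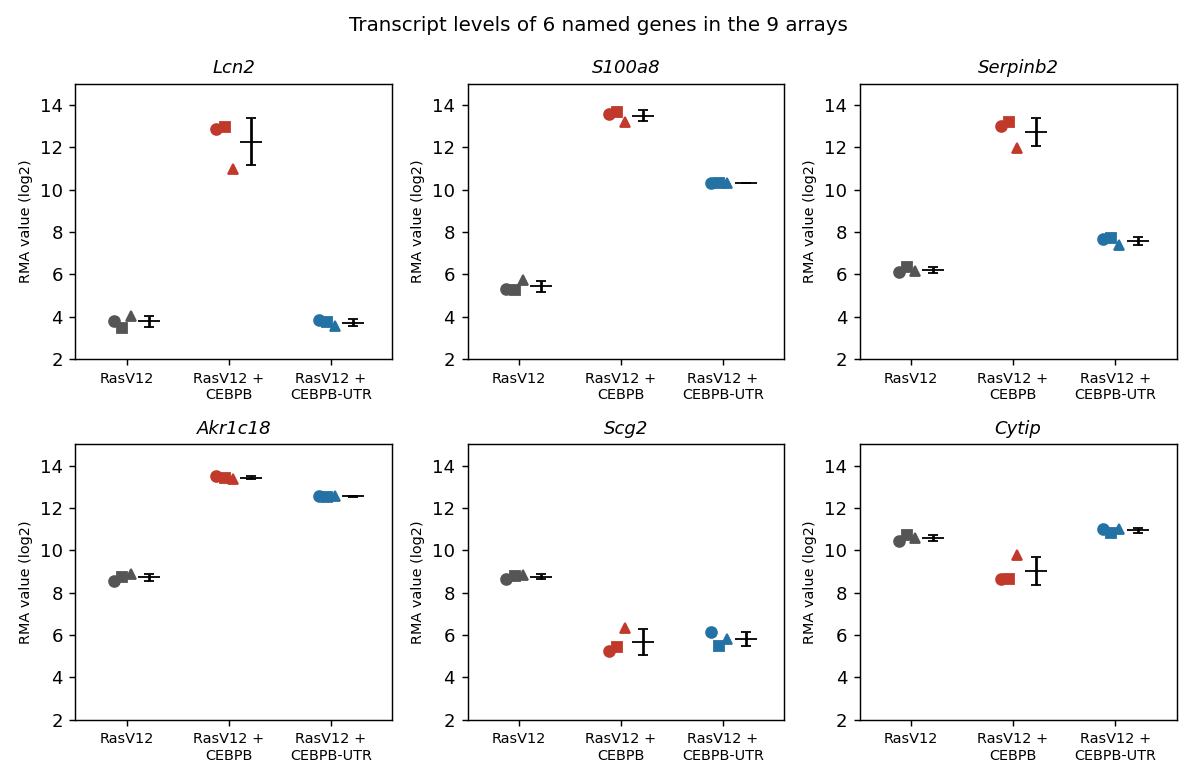
Log2 signal of 6 named genes on each of the 9 arrays, by group, with circles, squares and triangles for replicates 1, 2 and 3 and bars for the mean and SD (n = 3). Lcn2 had a mean of 12.27 in CEBPB against 3.77 in RasV12 and 3.72 in CEBPB-UTR, while S100a8 had 13.48, 5.43 and 10.32 in that order.

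CEBPB-UTR was next compared with RasV12 alone. S100a8, Akr1c18 and Stfa3 rose the most. S100a8 rose from 5.43 ± 0.27 to 10.32 ± 0.01 (mean log2 signal, SD, n = 3; adjusted p = 6.4e-09). Akr1c18, a progesterone-metabolising reductase, rose 14.1-fold (adjusted p = 1.1e-09), and Stfa3 had a log2 change of 3.77 ± 0.17 (SE, adjusted p = 4.3e-07). Lcn2, by contrast, had a log2 change of -0.05 ± 0.40 (SE, adjusted p = 0.95).

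The other large rises with CEBPB-UTR, as log2 change ± SE with n = 3 per group, were those of U90926 (3.51 ± 0.27), Rnase4 (2.78 ± 0.19), a secreted ribonuclease, Ptx3 (2.61 ± 0.22), Thbs1 (2.36 ± 0.09) and Bcl2l15 (2.29 ± 0.23), a Bcl-2 family member. The largest falls were those of Scg2 (-2.93 ± 0.24), Myh1 (-2.12 ± 0.32), Ang2 (-1.94 ± 0.13), a ribonuclease of the angiogenin family, Anpep (-1.92 ± 0.11), aminopeptidase N, Tpcn1 (-1.79 ± 0.17), an endolysosomal cation channel, Gas7 (-1.72 ± 0.19), Prkcb (-1.72 ± 0.16), protein kinase C beta, and Itgbl1 (-1.70 ± 0.24). Adjusted p for these genes ran from 1.7e-07 for Thbs1 to 0.0010 for Myh1. Called in the same direction were 1 of 2 probe sets for Ptx3, 2 of 3 for Tpcn1, 2 of 5 for Gas7 and 2 of 3 for Prkcb. At an adjusted p under 0.05, 1995 genes were higher and 1671 lower, 3666 in all. A further quantile normalization turned that balance, with 1824 higher and 1842 lower. Of the 3666 genes 99 rose and 75 fell at least 2-fold, and 18 rose at least 4-fold. With the offset of 32 these counts were 59, 40 and 6, and without the genes of below-median signal the 75 became 48.

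Of the 21 program lists 4 were called by camera, and fry called 3 of these 4, with adjusted p = 0.086 for the inflammatory list. Ribosome biogenesis genes rose in 8 of 22 cases and 0 fell, with Polr1b (0.54 ± 0.08), a subunit of RNA polymerase I, Utp20 (0.51 ± 0.09), Tsr1 (0.44 ± 0.09) and Noc4l (0.34 ± 0.08). 8 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.00052, and adjusted p = 0.28 with an estimated correlation). Contractile and SRF target genes fell in 11 of 20 cases, with Myh9 (-0.98 ± 0.07), nonmuscle myosin, Cnn2 (-1.06 ± 0.09), calponin, and Acta2 (-1.08 ± 0.10), smooth muscle actin, while the matricellular genes Ccn1 (1.90 ± 0.10) and Ccn2 rose. 2 rose and 11 fell adjusted over the list alone (camera adjusted p = 0.0013, and adjusted p = 0.16 with an estimated correlation). Among NRF2 targets 7 of 17 rose, with Nqo1 (0.45 ± 0.07), Hmox1 (0.59 ± 0.11) and Ugdh (0.43 ± 0.09), and Gsr (-0.34 ± 0.07) fell. 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0044, and adjusted p = 0.16 with an estimated correlation). The call ended when the genes of below-median signal were left out (adjusted p = 0.065). Inflammatory cytokines and chemokines rose in 7 of 23 cases, with Ccl7 (0.79 ± 0.08), Ptgs2 (1.16 ± 0.13), Cxcl5 (2.18 ± 0.29) and Il33 (0.65 ± 0.09), and Ccl8 (-0.35 ± 0.07) and Ccl5 fell. 8 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.018, and adjusted p = 0.47 with an estimated correlation).

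The other 17 program lists were not called by camera with CEBPB-UTR. Fry called 7 of them. Upward were p53 targets (fry adjusted p = 0.00025), the C/EBP family (0.00050), growth factors (0.0016), ribosomal proteins (0.0035), the extracellular matrix (0.0077) and acute phase genes (0.044), and downward were glycolysis and hypoxia genes (0.00030). The C/EBP list holds Cebpb, the introduced gene, which rose by 1.35 against a list median of 0.05. Its fry call is therefore no evidence of a response of the family. Of 21 acute phase and innate defence genes, 4 rose (S100a8, Ptx3, Tlr2 and Cp) and 1 fell (Mt1), 4 and 1 adjusted over the list alone, with adjusted p = 0.098. Of 25 mitosis genes, 5 rose (Kif11, Cenpe, Bub1, Ttk and Kif20a) and 1 fell (Foxm1), 7 and 3 adjusted over the list alone, with adjusted p = 0.075. In that list Kif11 changed by 0.61 ± 0.08 and Cenpe by 0.53 ± 0.08. Of 29 genes of DNA replication and S phase, 3 rose (Mcm10, Ccne2 and Rrm2) and 4 fell (E2f2, E2f1, Ccne1 and Mcm7), 3 and 4 adjusted over the list alone, with adjusted p = 0.37. Of 23 p53 targets and CDK inhibitors, 7 rose and 2 fell (Cdkn1b and Cdkn1a), 8 and 2 adjusted over the list alone, with adjusted p = 0.075. Of 17 growth factors, 5 rose (Hgf, Fgf7, Btc, Fgf2 and Ereg) and 4 fell (Pdgfa, Tgfb1, Pgf and Tgfb3), 6 and 4 adjusted over the list alone, with adjusted p = 0.19. The largest rises among them were those of Hgf (2.18 ± 0.13), Fgf7 (1.27 ± 0.08) and Btc (1.20 ± 0.08). Of 20 glycolysis and hypoxia genes, 1 rose (Slc2a1) and 6 fell, 1 and 7 adjusted over the list alone, with adjusted p = 0.075. Among these Egln3, a HIF prolyl hydroxylase, changed by -1.62 ± 0.08. Of 27 extracellular matrix genes, 7 rose and 3 fell (Col3a1, Col4a2 and Col6a1), 7 and 4 adjusted over the list alone, with adjusted p = 0.11.

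The remaining 10 of these lists gave counts in both directions or few calls. Of 18 matrix proteases and inhibitors, 4 rose (Timp1, Serpinb2, Mmp3 and Plaur) and 3 fell (Plat, Mmp11 and Mmp14), 4 and 3 adjusted over the list alone, with adjusted p = 0.91. Of 24 genes of the MAPK list, 7 rose and 5 fell (Spred3, Spred2, Fosb, Etv4 and Dusp4), 7 and 6 adjusted over the list alone, with adjusted p = 0.63. Of 24 ATF4 and unfolded protein response genes, 6 rose and 2 fell (Slc7a5 and Nupr1), 6 and 2 adjusted over the list alone, with adjusted p = 0.35. Of 16 cholesterol synthesis genes, 2 rose (Hsd17b7 and Sc5d) and 4 fell (Dhcr7, Lss, Srebf2 and Hmgcs1), 2 and 4 adjusted over the list alone, with adjusted p = 0.25. Of 19 adipocyte genes, 2 rose (Lpl and Pparg) and 0 fell, 1 and 0 adjusted over the list alone, with adjusted p = 1.00. Of 19 lysosomal genes, 1 rose (Ctsa) and 4 fell (Neu1, Lamp1, Lamp2 and Npc1), 1 and 4 adjusted over the list alone, with adjusted p = 0.87. With probe sets averaged, Lamp2 had a log2 change of 0.0164. Of 5 C/EBP family genes, 1 rose (Cebpb) and 0 fell, 1 and 0 adjusted over the list alone, with adjusted p = 0.18. Of 21 interferon-stimulated genes, 0 rose and 3 fell (Ifit1, Ifit3 and Mx1), 0 and 3 adjusted over the list alone, with adjusted p = 0.71. Of 19 Notch, Wnt and Hedgehog targets, 1 rose (Sfrp2) and 2 fell (Ccn4 and Nkd1), 1 and 2 adjusted over the list alone, with adjusted p = 0.85. Of 17 cytosolic ribosomal proteins, 1 rose (Rps9) and 1 fell (Rps16), 1 and 1 adjusted over the list alone, with adjusted p = 0.19.

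Of 14 macrophage markers, 1 rose (Ptprc) and 0 fell, 1 and 0 adjusted over the list alone, with adjusted p = 0.95. Of 14 epithelial markers, 0 rose and 1 fell (Cldn3), 0 and 0 adjusted over the list alone, with adjusted p = 0.46. Of 12 endothelial markers, 0 rose and 3 fell (Tie1, Egfl7 and Cdh5), 0 and 3 adjusted over the list alone, with adjusted p = 0.46. Of 13 skeletal muscle markers, 0 rose and 3 fell (Acta1, Chrna1 and Tnni1), 0 and 3 adjusted over the list alone, with adjusted p = 0.46. Of 14 fibroblast markers, 4 rose (Prrx1, Pdpn, Twist2 and Snai2) and 1 fell (Twist1), 5 and 1 adjusted over the list alone, with adjusted p = 0.46. The count of changed genes fell to 2212 without CEBPB-UTR replicate 1 and to 2327 without CEBPB-UTR replicate 2. It rose to 4001 without CEBPB replicate 3, which is in neither group compared but enters the shared spread.

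**Figure D3:**
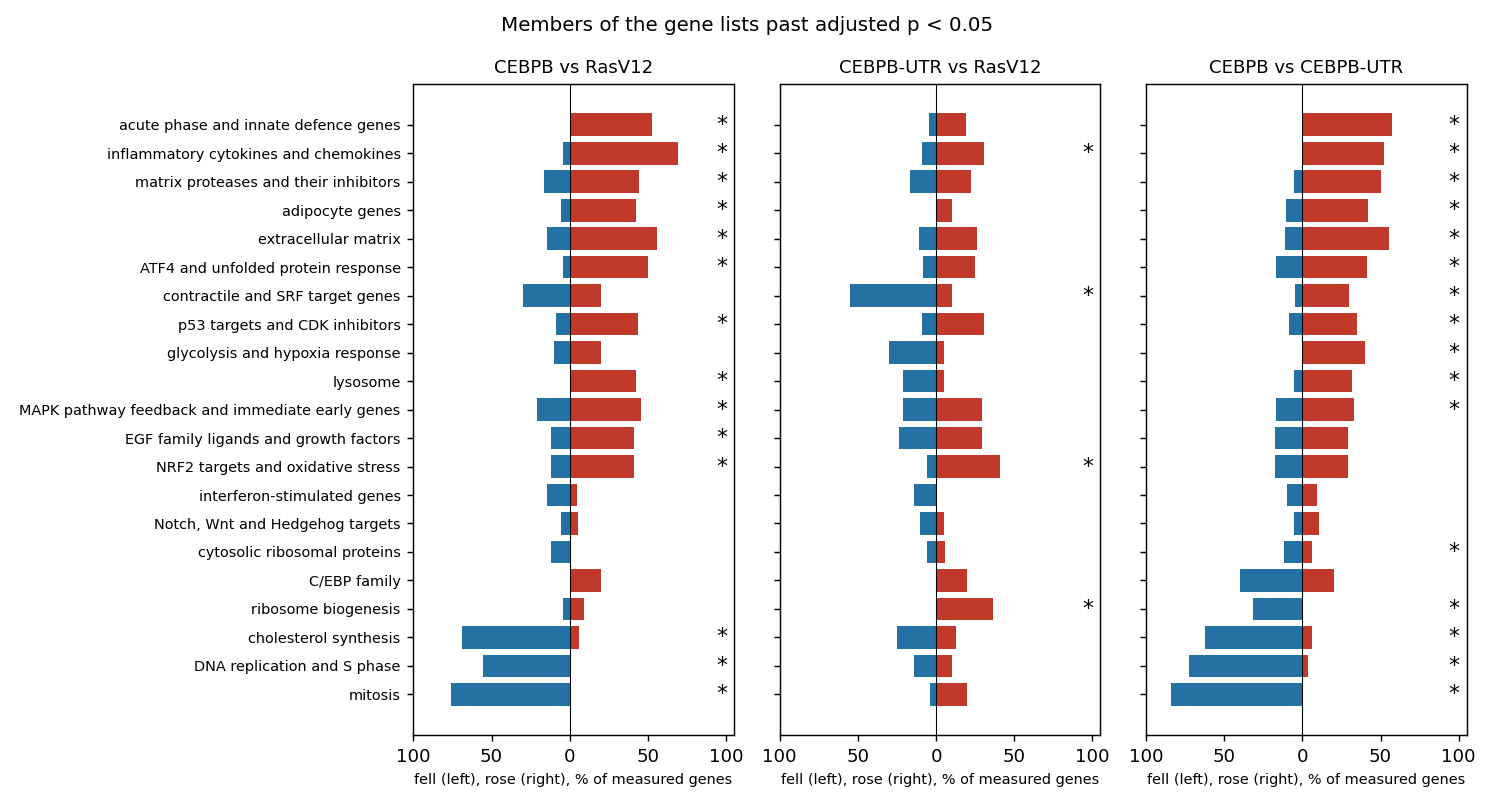
Percent of the measured members of each program list that rose (red, to the right) or fell (blue, to the left) at an adjusted p under 0.05, for each of the 3 comparisons, with an asterisk where the list was called by camera with its preset correlation. In CEBPB against CEBPB-UTR, 21 of 25 mitosis genes were lower.

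The direct comparison of CEBPB with CEBPB-UTR addresses the question of the series, how the UTR alters the program. Of the measured list members 12 of 21 defence genes and 12 of 23 cytokine genes were higher with CEBPB, with median log2 differences of 0.33 and 0.38 over the lists, and 21 of 25 mitosis genes were lower. Each of these 3 list calls was lost with an estimated correlation (adjusted p = 0.16). Among single genes, Lcn2 differed by 8.55 ± 0.40 (log2, SE; 12.27 ± 1.12 against 3.72 ± 0.16, mean log2 signal, SD, n = 3; adjusted p = 3.2e-07). Sprr1b differed by 7.51 ± 0.48 (SE, adjusted p = 3.7e-06) and Serpinb2 was 35.2-fold higher (adjusted p = 3.2e-07). Lcn2, Sprr1b, Cd36 and Il1a, the cytokine interleukin 1 alpha, were not called changed with CEBPB-UTR against RasV12, with log2 changes of -0.05, 0.13, 0.11 and 0.00. Their mean signals in RasV12 and in CEBPB-UTR ran from 2.69 to 4.48, below the median of 6.32. These signals are not shown to be above background, so the values near 0 do not show that CEBPB-UTR leaves these genes unchanged.

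The further named differences, as log2 change ± SE with n = 3 per group, were in Sprr2h (5.51 ± 0.68), Retnla (5.28 ± 0.18), Cd36 (5.12 ± 0.44), Il1a (4.81 ± 0.54) and Stfa3 (4.63 ± 0.17), all higher with CEBPB. Lower with CEBPB were Cytip (-1.91 ± 0.24), a cytohesin-interacting protein, Fgd4 (-1.66 ± 0.34), Tgfbi (-1.63 ± 0.17), a matrix protein induced by TGF-beta, Dlk1 (-1.60 ± 0.21), an inhibitor of adipocyte differentiation, Dixdc1 (-1.46 ± 0.28), Pkia (-1.45 ± 0.15), an inhibitor of protein kinase A, Spon2 (-1.40 ± 0.21) and Cd24a (-1.40 ± 0.12). Adjusted p for these genes ran from 2.9e-08 for Retnla to 0.0046 for Fgd4. Called lower were 3 of 5 probe sets for Fgd4 and 1 of 2 for Spon2. The 3 probe sets of Cd36 were all called higher, with log2 differences from 1.34 to 5.12. Without CEBPB replicate 3 the log2 differences were 9.19 for Lcn2, 8.31 for Sprr1b, 6.64 for Sprr2h, 5.84 for Cd36 and 5.71 for Il1a. At an adjusted p under 0.05, 1915 genes were higher and 2638 lower with CEBPB, 4553 in all, of which 207 were higher and 69 lower at least 2-fold, and 55 higher at least 4-fold. Without CEBPB replicate 3 the 69 became 121, with the offset of 32 it became 23 and with probe sets averaged 41. The 55 became 34 with the offset, and without the genes of below-median signal the 207 became 134 and the 55 became 29.

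Mitosis genes were lower with CEBPB than with CEBPB-UTR in 21 of 25 cases and higher in 0, with Kif11 (-1.05 ± 0.08), the spindle kinesin, Bub1 (-0.82 ± 0.08), a checkpoint kinase, Cenpe (-0.74 ± 0.08) and Cenpa (-0.65 ± 0.07). 0 were higher and 23 lower adjusted over the list alone (camera adjusted p = 1.4e-12, and adjusted p = 0.16 with an estimated correlation). Of 29 genes of DNA replication and S phase 21 were lower, with Pola1 (-0.69 ± 0.08), Mcm10 (-0.58 ± 0.07), Mcm3 (-0.58 ± 0.08) and Gins1 (-0.74 ± 0.10), and 1, Ccne1, was higher. 2 were higher and 22 lower adjusted over the list alone (camera adjusted p = 7.3e-09, and adjusted p = 0.16 with an estimated correlation). Ribosome biogenesis genes were lower in 7 of 22 cases and higher in 0, with Polr1b (-0.71 ± 0.08) and Dkc1 (-0.61 ± 0.10). 0 were higher and 7 lower adjusted over the list alone (camera adjusted p = 0.0032, and adjusted p = 0.36 with an estimated correlation). Leaving out the genes of below-median signal ended the call (adjusted p = 0.082). Cytosolic ribosomal proteins included 2 that were lower, Rpl14 (-0.46 ± 0.07) and Rps9 (-0.30 ± 0.06), and 1 that was higher, Rps16 (0.24 ± 0.08), of 17. 1 was higher and 4 lower adjusted over the list alone (camera adjusted p = 0.024, and adjusted p = 0.16 with an estimated correlation). That call ended without CEBPB replicate 3 (adjusted p = 0.051), without the genes of below-median signal (0.11), with all probe sets tested (0.096) and with probe sets averaged (0.064). Cholesterol synthesis enzymes were lower in 10 of 16 cases, with Fdft1 (-0.36 ± 0.06), Sqle (-0.38 ± 0.08) and Mvk (-0.35 ± 0.08), and Dhcr7 (0.47 ± 0.09) was higher. 1 was higher and 10 lower adjusted over the list alone (camera adjusted p = 0.0025, and adjusted p = 0.24 with an estimated correlation). Without the genes of below-median signal adjusted p was 0.057.

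Acute phase and innate defence genes were higher with CEBPB in 12 of 21 cases and lower in 0, with S100a8 (3.16 ± 0.14), Cd14 (1.65 ± 0.13) and Mt2 (1.26 ± 0.10), a metallothionein, beside Lcn2. 12 were higher and 0 lower adjusted over the list alone (camera adjusted p = 3.9e-08, and adjusted p = 0.16 with an estimated correlation). Inflammatory cytokines and chemokines were higher in 12 of 23 cases and lower in 0, with Lif (2.72 ± 0.10), Ccl2 (1.15 ± 0.09), Cxcl1 (3.94 ± 0.33) and Cxcl5 (3.06 ± 0.29). 13 were higher and 0 lower adjusted over the list alone (camera adjusted p = 2.0e-07, and adjusted p = 0.16 with an estimated correlation). Matrix proteases and inhibitors were higher in 9 of 18 cases, with Serpinb2, Mmp2 (0.68 ± 0.07), Mmp3 (2.09 ± 0.23) and Mmp10 (1.29 ± 0.19), and Timp3 (-0.45 ± 0.15) was lower. 11 were higher and 1 lower adjusted over the list alone (camera adjusted p = 6.3e-05, and adjusted p = 0.16 with an estimated correlation). Of 27 extracellular matrix genes 15 were higher, with Thbs1 (1.77 ± 0.09), Tnc (1.12 ± 0.09), tenascin C, Fn1 (0.94 ± 0.08) and Col5a2 (1.06 ± 0.12), and Fbln2, Col1a2 and Col6a2 were lower. 16 were higher and 3 lower adjusted over the list alone (camera adjusted p = 9.2e-05, and adjusted p = 0.16 with an estimated correlation). Contractile and SRF target genes were higher in 6 of 20 cases, with Itga5 (1.65 ± 0.17), the fibronectin receptor subunit, Acta2 (0.95 ± 0.10), Ccn1 (0.84 ± 0.10) and Myh9 (0.50 ± 0.07), and Vcl was lower. 7 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0036, and adjusted p = 0.16 with an estimated correlation).

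Glycolysis and hypoxia genes were higher with CEBPB in 8 of 20 cases and lower in 0, with Adm (1.43 ± 0.13), adrenomedullin, Hk1 (0.63 ± 0.08), Pfkp (1.00 ± 0.13) and Ndrg1 (0.54 ± 0.11). 9 were higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0025, and adjusted p = 0.16 with an estimated correlation). Adipocyte genes were higher in 8 of 19 cases, with Lpl (3.66 ± 0.30), Cd36, Retn (1.12 ± 0.11) and Dgat1 (0.84 ± 0.10), and Scd1 and Fasn were lower. 8 were higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0035, and adjusted p = 0.16 with an estimated correlation). Lysosomal genes were higher in 6 of 19 cases, with Neu1 (0.69 ± 0.08), Ctsk (0.73 ± 0.09), Lamp1 (0.48 ± 0.06) and Ctsd (0.33 ± 0.07), and Glb1 was lower. 8 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0069, and adjusted p = 0.16 with an estimated correlation). Among p53 targets and CDK inhibitors 8 of 23 were higher, with Gadd45a (1.92 ± 0.21), Btg2 (1.23 ± 0.12) and Cdkn1a (0.57 ± 0.08), and 2 were lower, Zmat3 (-0.56 ± 0.08) and Sesn1. 9 were higher and 2 lower adjusted over the list alone (camera adjusted p = 0.012, and adjusted p = 0.16 with an estimated correlation). With probe sets averaged Cdkn1a had the other sign, -0.168, and the list was not called (adjusted p = 0.10), nor was it with all probe sets tested (0.10). Of 24 ATF4 and unfolded protein response genes 10 were higher, with Ddit3 (1.14 ± 0.12), Ddit4 (0.70 ± 0.08) and Dnajb9 (0.68 ± 0.09), and 4 were lower, Psat1 (-0.52 ± 0.08), Shmt2, Xbp1 and Pdia4. 11 were higher and 4 lower adjusted over the list alone (camera adjusted p = 0.022, and adjusted p = 0.49 with an estimated correlation). With all probe sets tested adjusted p was 0.069. Of 24 genes of the MAPK list 8 were higher, with Junb (1.03 ± 0.09), Spry4 (0.97 ± 0.10), Ier3 (0.81 ± 0.09) and Spred3 (0.79 ± 0.08), and Egr3, Spred1, Etv5 and Ier2 were lower. 8 were higher and 4 lower adjusted over the list alone (camera adjusted p = 0.024, and adjusted p = 0.16 with an estimated correlation). The MAPK call ended without CEBPB replicate 3 (adjusted p = 0.051), without CEBPB-UTR replicate 3 (0.078) and with all probe sets tested (0.14).

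Uncalled by camera in this comparison were 5 program lists. Fry called 2 of them, the C/EBP family downward (fry adjusted p = 0.0022) and the growth factors upward (fry adjusted p = 0.012). The C/EBP call includes the introduced gene, Cebpb, with a log2 difference of -1.20 by 1418901_at. Of 17 growth factors, 5 were higher (Ereg, Nrg1, Fgf7, Hbegf and Vegfc) and 3 were lower (Btc, Tgfb3 and Fgf2), 5 and 3 adjusted over the list alone, with adjusted p = 0.075. Betacellulin, Btc, differed by -1.37 ± 0.08 and epiregulin, Ereg, by 0.71 ± 0.08. Of 5 C/EBP family genes, 1 was higher (Ddit3) and 2 were lower (Cebpb and Cebpg), 1 and 2 adjusted over the list alone, with adjusted p = 0.37. Of 17 NRF2 targets, 5 were higher (Sod2, Hmox1, Slc7a11, Gsr and Abcc1) and 3 were lower (Gsta4, Gstm1 and Gclm), 5 and 5 adjusted over the list alone, with adjusted p = 0.86. Of 21 interferon-stimulated genes, 2 were higher (Cxcl10 and Ifit1) and 2 were lower (Ifit2 and Stat2), 2 and 2 adjusted over the list alone, with adjusted p = 0.83. Of 19 Notch, Wnt and Hedgehog targets, 2 were higher (Lef1 and Nkd1) and 1 was lower (Sfrp2), 2 and 1 adjusted over the list alone, with adjusted p = 0.91.

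Of 14 macrophage markers, 3 were higher (Lyz2, Cd53 and Cd68) and 1 was lower (Ptprc), 3 and 1 adjusted over the list alone, with adjusted p = 0.38. Of 14 epithelial markers, 1 was higher (Cldn3) and 0 were lower, 0 and 0 adjusted over the list alone, with adjusted p = 0.46. Of 12 endothelial markers, 3 were higher (Egfl7, Cdh5 and Tie1) and 0 were lower, 3 and 0 adjusted over the list alone, with adjusted p = 0.38. Of 13 skeletal muscle markers, 1 was higher (Acta1) and 0 were lower, 0 and 0 adjusted over the list alone, with adjusted p = 0.93. Of 14 fibroblast markers, 3 were higher (Twist1, Pdpn and Meox1) and 4 were lower (Pdgfra, Prrx1, Pdgfrb and Twist2), 3 and 5 adjusted over the list alone, with adjusted p = 0.74.

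Many genes were called in the same direction with both constructs against RasV12. Higher with both were 588 genes and lower with both 640, 1228 in all, where lists of the same sizes drawn independently would share 333. Opposite calls were made for 154 genes, 47 higher with CEBPB and lower with CEBPB-UTR and 107 the other way round, where independent lists would give 341. Of the 588 genes higher with both, 247 differed between the constructs, 201 of them being higher with CEBPB. Of the 98 genes that rose at least 4-fold with CEBPB, 61 were called higher with CEBPB-UTR, 17 of them at least 4-fold, and 94, which were chosen on the same CEBPB arrays, were called higher in CEBPB than in CEBPB-UTR. Of the 18 genes that rose at least 4-fold with CEBPB-UTR, 14 were called higher with CEBPB than with CEBPB-UTR and 0 lower. Across genes the log2 changes of the 2 comparisons had a covariance of 0.0616, against a mean of 0.00550 and a highest value of 0.0328 in 100 simulations in which unchanged groups were compared with the same controls. Pearson r across genes lay within the simulated range, 0.528 against a mean of 0.468 and a highest value of 0.960. So did the share of genes of the same sign, 62.4% against a mean of 67.0% and a highest value of 90.1%. Genes called the same way in both numbered at most 0 in the simulations, against 1228. Groups simulated without change are built to give few calls, so this 0 does not measure what the shared controls add among called genes. Both comparisons share the RasV12 arrays, and 3 controls cannot be divided evenly between them, so that part of the overlap may come from the shared controls. None of the 3 groups is labelled as holding RasV12 with an empty second retrovirus. An effect of the second retrovirus or its selection would also be shared, and cannot be told apart from that of C/EBPβ.

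**Figure D4:**
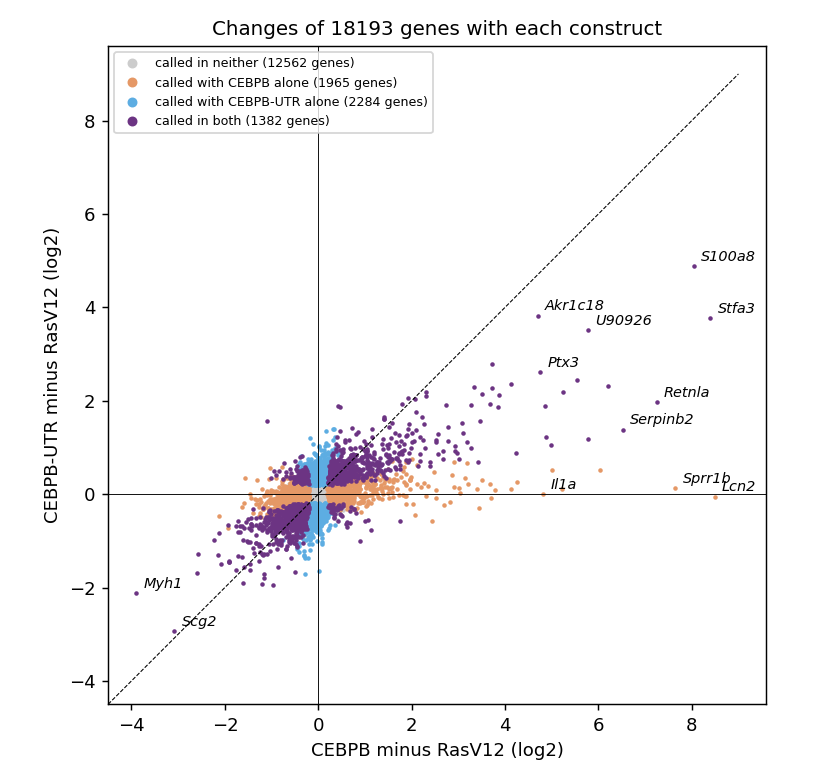
Log2 change of each of the 18193 genes with CEBPB (horizontal axis) and with CEBPB-UTR (vertical axis), both against RasV12, coloured by the comparison in which the gene was called. Called in both were 1382 genes, with CEBPB alone 1965 and with CEBPB-UTR alone 2284.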

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

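The tests of a CEBPB-UTR admixture by a single share, of degraded RNA, of the left-out arrays, of the Cebpb level in CEBPB replicate 3, of the part of the mRNA read, of saturation, of the Cebpb mRNA level with CEBPB-UTR and of genes chosen on other arrays were chosen only after the result was seen.

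In 154 genes the 2 constructs gave opposite calls against RasV12, fewer than the 341 that independent lists would give. Each comparison was adjusted on its own, so the share of false calls among these 154 genes was not controlled. An opposite direction is therefore not shown for every one of them. The difference between the constructs is the sum of the opposite changes in the same fit, with the same SE, so that its own call in these genes adds no evidence. The largest differences were those of Agtr2, with a log2 change of -1.10 with CEBPB and 1.58 with CEBPB-UTR, and of Sprr1a, with 1.76 and -0.57. The mean log2 signals of Agtr2 and Sprr1a over all arrays, 4.49 and 6.18, lay below the median of 6.32. The opposite changes of Agtr2 and Sprr1a are therefore not shown to be above background. Grina changed by 0.89 and -0.99, and Cthrc1 by -0.85 and 0.50. The mean signals of Grina and Cthrc1, 9.95 and 7.73, lay above that median.

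Among the 10092 probe sets that carry no single gene symbol, which the counts, lists and named genes above do not use, 21 rose at least 4-fold with CEBPB against RasV12. The largest rises were those of 1422411_s_at, by 4.67 on the log2 scale against -0.10 with CEBPB-UTR, 1418423_s_at, by 4.67 against 0.23, and 1421811_at, by 4.20 against 2.80.

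CEBPB replicate 3 lay between the other CEBPB arrays and the other groups: of 358 genes that rose at least 2-fold on replicates 1 and 2, 305 (85.2%) were lower on replicate 3 than on both, and of 197 that fell, 185 (93.9%) were higher, where choosing genes in the same way without each CEBPB-UTR array in turn gave 24.0% to 45.7% and 32.9% to 46.6%. If signals are linear in the amount of RNA, an admixture of RasV12 cells or RNA would bring rising and falling genes to 1 share. Their median implied shares were 0.417 and 0.274, a difference of 0.143, which argues against such an admixture only if that holds. The 95% interval, 0.113 to 0.194, came from resampling the genes of this 1 array. Genes are not independent, so it may be too narrow. For an admixture of CEBPB-UTR the planned test met the prediction of that explanation, with a coefficient of 0.296 towards CEBPB-UTR. Its 95% interval, from resampling genes, was 0.226 to 0.372. A weaker response to the construct that resembles that of CEBPB-UTR would also give a positive coefficient. The coefficient therefore does not tell such a response from an admixture. In the test added later, the best single share of 44% left 40.1% of 379 genes outside their 95% prediction interval. Another array without any share had at most 23.2%. These genes were chosen on the other 8 arrays, and the intervals of those arrays took in the spread of replicate 3. The 2 percentages are therefore not alike. Neither Cebpb probe set moved towards CEBPB-UTR on replicate 3. There 1418901_at read 10.59, against 10.57 and 10.64 on replicates 1 and 2 and a mean of 11.80 in CEBPB-UTR. 1427844_a_at read 10.04, against 10.13 and 10.19 and a mean of 10.66. If signals are linear in the amount of RNA, these values argue against a share as large as 44%. A smaller admixture of CEBPB-UTR stays open. Degraded RNA is argued against by the difference between the 3' and 5' actin probe sets, 0.154, which lay within the 0.0858 to 0.229 of the other 8 arrays. A weaker expression of the construct stays open, as 1427844_a_at was lower there by a log2 value of -0.121, less than its pooled SD of 0.129, and a biological difference between cultures was not tested.

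The Cebpb probe sets moved apart with CEBPB, where 1427844_a_at rose by 1.04 more than 1418901_at on the log2 scale (lower bound of the 95% interval 0.825). This difference is consistent with a CEBPB construct that lacks the part of the mRNA read by 1418901_at, a hypothesis found on the same data and open until the probe sequences are aligned with the constructs. With CEBPB-UTR 1427844_a_at also rose more than 1418901_at, by 1.74 against 1.35, which a part missing from the CEBPB construct would not explain. Saturation of 1418901_at is argued against by its rise of 1.35 with CEBPB-UTR.

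Of the 98 genes that rose at least 4-fold with CEBPB, 94 were called lower with CEBPB-UTR than with CEBPB, but they were chosen on the same CEBPB arrays. Chosen without 1 CEBPB array and compared on that array, 89 of 90, 86 of 87 and 115 of 120 genes were lower in the mean of CEBPB-UTR, for replicates 1, 2 and 3 in turn. Of the 18 genes chosen by a rise of at least 4-fold with CEBPB-UTR, 14 were called lower with CEBPB-UTR than with CEBPB and 0 higher. A small admixture of CEBPB cells in CEBPB-UTR samples would give every gene the same share of its CEBPB rise, but 63 of the 98 exceeded, beyond their error, the 0.217% that Lcn2 allows, with shares of 10.8% for S100a8, 52.5% for Akr1c18 and 90.4% for Hgf. Less Cebpb mRNA with CEBPB-UTR is argued against by 1427844_a_at, for which the log2 difference of CEBPB minus CEBPB-UTR was -0.543. What the constructs hold is not given and no protein was measured, so the cause of the pattern stays open, and no biological explanation was tested.

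The 6 arrays of each comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split was the 1 of 10 with as many genes in each comparison, 3347, 3666 and 4553, and the highest of the other splits called 0. Each other split mixes arrays of both groups, so that a difference between the groups enters its spread and removes calls. The 0 is therefore no evidence on a grouping by chance.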

How the results depend on the processing

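All alternatives were planned. The counts of changed genes stayed within 1.5 times their values under 9 of the 10 alternatives other than leaving out single arrays. With all probe sets tested they were 5857, 7262 and 9328, in the order CEBPB against RasV12, CEBPB-UTR against RasV12 and CEBPB against CEBPB-UTR, and 2073 called the same way against RasV12, because more features were tested. With 1 array left out at a time, and so fewer samples, they ran from 2401 to 3592, from 2212 (without CEBPB-UTR replicate 1) to 4001, from 3228 to 5052 and from 870 to 1417. Counts at a fold threshold moved more, and 8 of the 9 moved by over 1.5 times under some setting, most with the offset of 32 and without the dimmer genes, as given beside each count. With the replicate number as a block the counts of changed genes were 2863, 3002, 4040 and 1023. Of the values of named genes, 2 reversed, both with a gene's probe sets averaged: Lamp2 with CEBPB-UTR against RasV12, with 0.0164, and Cdkn1a with CEBPB against CEBPB-UTR, with -0.168. In both the cause was not tested. Averaging also ended the calls of 18 of 349 results of named genes. Calls of lists ended in 34 of 78 tests with an estimated correlation, in 1 with fry, and in 5 each with the dimmer genes left out and with all probe sets. Calls were also gained, 14 with fry and, under other settings, 10, of which 1 with CEBPB against RasV12 (ribosomal proteins), 8 with CEBPB-UTR against RasV12 (acute phase, mitosis, p53 targets, growth factors, extracellular matrix, glycolysis, ATF4 and ribosomal proteins) and 1 between the constructs (growth factors). Under a further quantile normalization and under centring each array, 78 of 78 list results kept their side of the threshold. The offset of 32 ended the calls of 10 of 355 results of named genes and added 3. Leaving out the dimmer genes ended 0 of the 265 results that remained and added 10. The results of dim genes dropped out, and testing fewer genes can ease the adjustment. The 0 therefore does not show that results of dim genes hold.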

Other observations

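The tests of gene families by symbol were chosen only after the result was seen. Small proline-rich proteins, precursors of the cornified envelope of squamous epithelia, rose as a family with CEBPB. Of 9 measured Sprr genes 6 rose at least 2-fold against RasV12, Sprr1a, Sprr1b, Sprr2h, Sprr2i, Sprr2j-ps and Sprr2k (one-sided Fisher's exact test, adjusted p = 3.8e-06 over 3426 tests of families, directions and comparisons). The same 6 were at least 2-fold higher in CEBPB than in CEBPB-UTR (one-sided Fisher's exact test, adjusted p = 5.6e-07). Both tests count the genes of a family as independent draws and measure no spread between arrays. Whether probe sets of related members read the same transcripts was not tested. The epithelial marker list had 0 of 14 members called with CEBPB against RasV12.

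The growth factor list was not called between the constructs by camera (adjusted p = 0.075), but was called by fry (adjusted p = 0.012) and by camera with only the arrays compared (0.040), without RasV12 replicate 1 (0.045), without CEBPB replicate 3 (0.038) and with all probe sets (0.0083). With an estimated correlation its adjusted p was 0.25. The values of 3 of its members differ in pattern. Btc, betacellulin, had a log2 change of 1.20 ± 0.08 with CEBPB-UTR and -0.17 ± 0.08 with CEBPB against RasV12 (SE, n = 3 per group), with a difference between the constructs of -1.37 ± 0.08 (adjusted p = 2.6e-06). Hgf, hepatocyte growth factor, had 2.30 ± 0.13 with CEBPB and 2.18 ± 0.13 with CEBPB-UTR, and a difference of 0.11 ± 0.13 (adjusted p = 0.57). Ereg, epiregulin, had 1.34 ± 0.08 and 0.63 ± 0.08, and a difference of 0.71 ± 0.08 (adjusted p = 0.00011).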
